A study of Mus musculus with 12 samples.

How the data were processed

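Primary mouse embryonic fibroblasts (MEFs, cultures grown from embryos) of the C57BL6 strain, wild type (WT) or SIRT7 knockout (KO), female or male, were profiled by RNA sequencing as 4 groups of 3 libraries. Per the labels' protocols, RNA was extracted with TRIZOL reagent, and an external provider (NovaGene) selected polyA RNA, made the libraries and sequenced them. The submitters' processing notes name FastQC 0.11.3, Trimmomatic 0.36, HISAT2 2.1.0, SAMtools 0.1.19, StringTie 1.3.3 and DESeq2 1.32.0, and the genome builds mm10 and GRCm38, with no role or order given. The deposited table holds raw read counts per gene, 1 column per library, for 24421 genes named by chromosome and symbol. The values are whole numbers with a different sum in every library. The name given to the deposited count table includes the words featureCounts and calibrated, but the table used here has no spike-in genes, so no absolute scale could be set. The strand setting, the version of the counting program and the treatment of reads with several positions are not given in the sources used here. Low counts were mostly even. Among counts of 2 to 19, 80.9% to 89.8% were even, with a median of 85.0% over libraries, so both reads of a pair may have been counted singly, which would make counting error larger than the counts alone imply. Genes that overlap on opposite strands, and near-identical copies, could share reads.

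From these counts, genes with too few reads for a test were removed with edgeR's filterByExpr by group, which left 15613 genes (63.9%). Library sizes were scaled by TMM, and 1 robust quasi-likelihood model with a mean for each of the 4 groups was fitted to all 12 libraries (edgeR 4.0.16 with limma 3.58.1 in R 4.3.3), so all comparisons share 1 estimate of the spread, with 8 residual degrees of freedom and a prior of 2.80. There were 6 comparisons: KO against WT in females, in males and averaged over both sexes, the difference between the female and male KO effects, and female against male libraries within WT and within KO. Each gene was tested with glmQLFTest, two-sided, and p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Log2 fold changes are given with their standard error (SE) from the same fit. Levels are CPM (counts scaled to a common library total) computed from the deposited counts with TMM-scaled library sizes, as mean and SD over 3 libraries. No label says that the replicates are separate animals or cultures, so p-values measure only the spread between these samples, which may be technical in part. Replicates of a group differed by 18.9 to 122 times the sampling variance (chi-square per degree of freedom), so no library was a copy of another in its group. The lowest values were 18.9 for Female_KO 2 and Female_KO 3 and 22.3 for Male_KO 2 and Male_KO 3. Whether the libraries of these pairs share an origin is not given by the labels.

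The comparisons, the alternatives, the rule for named genes and 34 gene lists were fixed before the data were examined. The rule names Sirt7, Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty always. It then names up to 8 genes in each direction with an adjusted p below the threshold, a mean CPM of 1 or more and no overlap between the libraries of both groups, a property that chance gives to 10% of genes in 3 against 3. Where fewer than 5 genes passed, the 5 genes of smallest p are given as values, and for each list named in the text up to 4 members of smallest p. The lists cover X inactivation escape genes, the X inactivation centre, Xist silencing factors, Y-linked genes and sirtuins. Further lists cover cytosolic ribosomal proteins, mitochondrial ribosomal proteins, RNA polymerase I and rRNA processing, p53 targets, S phase and DNA replication, G2 and mitosis, DNA repair, and the unfolded protein and integrated stress response. The rest are interferon response, inflammatory and senescence-associated secretion, extracellular matrix, contractile and TGF-beta response, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, imprinted, Hox, germline and histone genes, and markers of macrophages, endothelium, skeletal muscle, smooth muscle, neurons, glia, epithelium, adipocytes, chondrocytes and erythroid cells. Of these, 33 had 5 or more tested genes. The Y-linked list had 4 and was not tested as a list.

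Lists were tested with limma's camera on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 33 lists within a comparison, again with the correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance one way. A list effect is the mean log2 fold change of its tested members. X-linked genes were set against autosomal genes by the difference of their median log2 fold changes, tested with camera over 537 X-linked and 15072 autosomal genes. For each library the log2 ratio of the median CPM of X-linked genes to that of autosomal genes was computed over 447 and 12517 genes with a mean CPM of 1 or more, and groups were compared with exact two-sided permutation tests. With 3 against 3 libraries there are 20 arrangements and the smallest p is 0.1. Over both sexes there are 400 arrangements within sex and the smallest p is 0.005. Gene positions are those of GENCODE vM21 on GRCm38, where 15488 of the tested genes (99.2%) were placed. By symbol, 15566 (99.7%) of the tested genes matched RefSeq.

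The gene test was tested on simulated data. Counts were drawn for the 15613 tested genes from their means over all 12 libraries and the spread of the 4-group model. The filter then kept 15422 genes. Of genes changed 1.5-fold, 17 of 67 (25.4%) were recovered for the female KO comparison, against 37 of 67 (55.2%) at 2-fold and 58 of 66 (87.9%) at 4-fold, with 4 false calls. All these genes were changed in the same simulation, which loosens the Benjamini-Hochberg threshold. Where few genes change, as in the real comparison, recovery may be lower. In simulations of the same comparison over 15613 genes with every X-linked gene shifted, camera gave a p under 0.05 in 0 of 8 at no shift and in 8 of 8 at 1.05-fold, 1.1-fold and 1.2-fold. The simulated genes varied independently, so this sensitivity is an upper limit for real genes. Library totals were 41989269 to 46031948 counts (median 44962240), and 17693 to 18337 genes were detected per library. A gene at 1.85 CPM, the level of Sirt7 in female KO libraries, rests on 74 to 88 counts.

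The alternatives tried were DESeq2's size factors within edgeR, TMM over autosomal genes, no low-count filter or a mean CPM of 1 or more, the replicate block, a minimum fold of 1.2, the DESeq2 1.42.0 Wald test, fits to only the 6 libraries of a pair of groups, camera with an estimated correlation, X-linked genes without escape genes, a mean CPM of 5 or more or summed CPM for the X ratio, and leaving out each library in turn. After the data were seen, a fit without the libraries Female_KO 1 and Male_WT 3 (also with an estimated correlation), a fit to counts divided by 2 and the lists that hold Xist without it were added. Exact permutation tests of the list scores were not among the planned tests and were added too. Alternatives that scale to spike-ins were not run. Library names give the group and the replicate number from the labels.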

Results

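Gene expression was measured in 12 libraries of primary mouse embryonic fibroblasts. WT and SIRT7-KO cells of female and male origin made up 4 groups of 3 libraries each. SIRT7 is a nuclear deacylase of the sirtuin family, best known for its role at ribosomal DNA and RNA polymerase I. The series addresses the part that SIRT7 plays in dosage compensation, the silencing of an X chromosome in female cells that equalises X-linked expression with male cells, so the comparisons are KO against WT in each sex, the difference between these effects, X-linked against autosomal genes, and female against male cells of each genotype. Totals were 41989269 to 46031948 counts per library, X-linked genes took 3.23% to 3.34% of the counts, and the 100 most abundant genes took 12.2% to 14.2%. Of the 24421 genes listed, 15613 were tested.

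Sirt7 was strongly reduced in every KO library. It had 74 to 88 counts in female KO and 71 to 82 in male KO libraries, against 1101 to 1302 in female WT and 1188 to 1543 in male WT libraries. The level fell from 26.8 ± 1.86 to 1.85 ± 0.172 CPM in females and from 29.2 ± 4.86 to 1.78 ± 0.186 CPM in males (SD, n = 3), which left 6.91% and 6.10% of the WT level. The gene lies on chromosome 11 at 120618372 to 120625240 (GRCm38, minus strand). Its annotated start, at the higher coordinate, overlaps the next gene, Mafg, by position. Which part of the gene was removed is not given in the sources used here, so whether the remaining counts lie in a part left in place is not known here. Xist, the long noncoding RNA that coats and silences the inactive X chromosome, had 20603 to 29505 counts in female and 58 to 80 in male libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 1037 to 3982 counts in male and 0 to 14 in female libraries. Sirt7, Xist and the Y-linked genes thus matched the label of every library.

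Outside these genes, the main variation between libraries did not follow genotype or sex. The first principal component of log2 CPM held 30.3% of the variance and set Female_KO 1 (score 64.7) and Male_WT 3 (62.3) apart from the other 10 libraries (-31.9 to 14.6). The second held 20.3% and set Male_KO 2 (-41.3) and Male_KO 3 (-50.8) apart. As list scores (mean log2 deviation of the members from their mean over all libraries), G2 and mitosis genes were at -0.50 in Female_KO 1 and -0.35 in Male_WT 3, against -0.19 to 0.37 in the others. S phase genes were at -0.46 and -0.32 (others -0.21 to 0.33), and p53 targets at 0.38 and 0.46 (others -0.34 to 0.20). Extracellular matrix genes were at -0.29 and -0.52 (others -0.31 to 0.38), interferon response genes at -0.39 and -0.64 (others -0.29 to 0.72) and cholesterol synthesis genes at -0.49 and -0.37 (others -0.41 to 0.81). Among cell type markers, those of macrophages were at 1.03 and 1.01 (others -1.26 to 0.70), those of glia at 1.13 and 1.03 (others -0.78 to 0.54), those of skeletal muscle at -1.91 and -1.74 (others -2.00 to 1.60), those of epithelium at -1.06 and -1.29 (others -0.91 to 1.51) and those of chondrocytes at -0.53 and -0.50 (others -0.42 to 1.73).

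**Figure D1:**
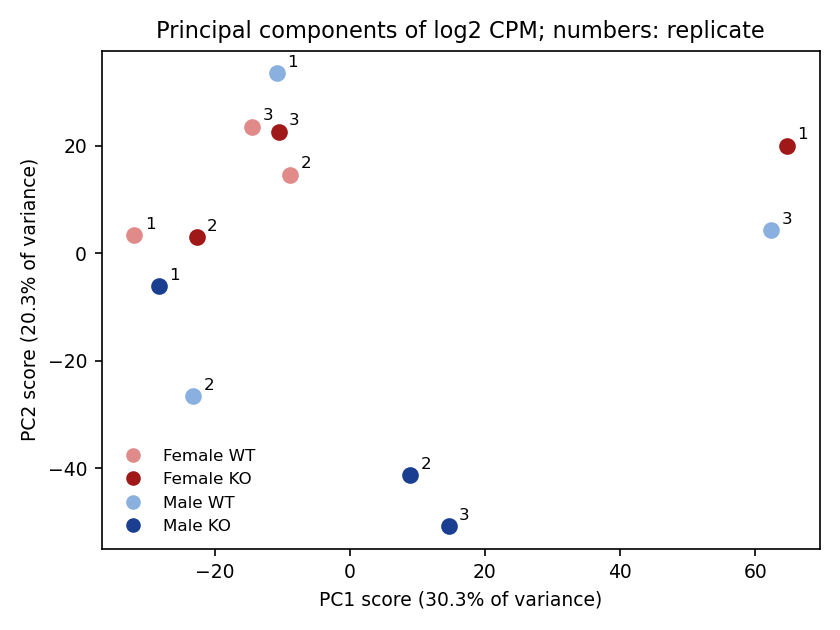
Scores of the 12 libraries on the first and second principal components of log2 CPM, each axis with its share of the variance, coloured by group and numbered by replicate. Female_KO 1 and Male_WT 3 lie at 64.7 and 62.3 on the first component, and all other libraries lie between -31.9 and 14.6.

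In female cells, 3 genes changed between WT and KO libraries, Sirt7 and a pair of genes near it on chromosome 11. Sirt7 fell by 3.85 ± 0.16 on the log2 scale (SE, adjusted p 1.19e-06). Pcyt2, which encodes the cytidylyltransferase of phosphatidylethanolamine synthesis, fell from 55.0 ± 9.46 to 12.3 ± 3.94 CPM (SD, n = 3), a log2 change of -2.16 ± 0.25 (adjusted p 0.0240). Fam195b (Mcrip1 in the reference annotation), a corepressor-interacting protein regulated by MAP kinase, rose 1.87-fold, from 59.8 ± 3.62 to 112 ± 8.81 CPM, a log2 change of 0.91 ± 0.10 (adjusted p 0.0240). Among the 5 genes of smallest p, P4hb, a protein disulfide isomerase, had a log2 change of 0.58 ± 0.09 (adjusted p 0.292), and Dctd, the dCMP deaminase of nucleotide synthesis, one of -0.92 ± 0.17 (adjusted p 0.635). Xist had a log2 change of -0.07 ± 0.11 (adjusted p 0.856), from 581 ± 55.6 to 552 ± 85.1 CPM. Its sign turned without Female_WT 1 (0.0036) and without Female_KO 1 (0.04). Tests are edgeR's quasi-likelihood test, in which 1127 genes had an unadjusted p under 0.05 (781 by chance). DESeq2 called 7 genes, 5 of them on chromosome 11, and P4hb and Dctd were among the 7. Sirt7 was called whichever library was left out. Fam195b and Pcyt2 were both lost without Female_WT 1 (adjusted p 0.212 and 0.113), Female_WT 2 (0.225, 0.141), Female_WT 3 (0.129 for both), Female_KO 3 (0.237, 0.262), Male_WT 1 (0.0548 for both), Male_WT 3 (0.0625 for both) or Male_KO 2 (0.0552 for both), each time with a count of 1. Fam195b alone was lost without Female_KO 2 (0.168). Without Female_KO 1, 6 genes were called, with Dctd, Rwdd4a and Wwc2 added. These 3 neighbours on chromosome 8 were lower in Female_KO 2 (log2 deviations of -0.93, -0.83 and -0.87) and Female_KO 3 (-0.93, -0.74 and -0.77), but at -0.27, 0.19 and 0.33 in Female_KO 1. Without both Female_KO 1 and Male_WT 3, 5 genes were called, with the same 3 added and Pcyt2 lost (adjusted p 0.0842). In a fit to the 6 female libraries alone, Sirt7 was the 1 gene called (Fam195b 0.111, Pcyt2 0.402), and with a minimum fold of 1.2 Fam195b was lost (0.0802).

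As lists, genes of cell division and of ribosome production were lower in female KO libraries by camera with its preset correlation. No list call held with an estimated correlation. In 10 of 10 splits of the female libraries, the real one among them, camera called as many lists, so the number of calls does not set KO apart. All 70 tested genes of G2 and mitosis had a negative change, with a mean of -0.44 (camera adjusted p 1.85e-25; adjusted p = 0.736 with an estimated correlation). Examples are the securin Pttg1 (-0.40 ± 0.13), survivin Birc5 (-0.45 ± 0.15) and the checkpoint gene Mad2l1 (-0.46 ± 0.16). All 62 genes of S phase and DNA replication were also negative, with a mean of -0.37 (3.80e-19; 0.736 with an estimated correlation), among them the primase Prim1 (-0.58 ± 0.19) and DNA polymerase epsilon Pole (-0.51 ± 0.18). Of 79 genes of RNA polymerase I and rRNA processing, 75 were negative, with a mean of -0.26 (6.50e-24; 0.736 with an estimated correlation), among them dyskerin Dkc1 (-0.60 ± 0.18) and the helicase Ddx52 (-0.23 ± 0.07). Of 70 DNA repair genes 53 were negative, with a mean of -0.17 (2.60e-06; 0.736 with an estimated correlation), among them Fancl (-0.55 ± 0.13) and Bard1 (-0.63 ± 0.22). Of 40 p53 targets 39 were positive, with a mean of 0.44 (3.01e-09; 0.736 with an estimated correlation), among them the apoptosis genes Perp (1.34 ± 0.51), Bbc3 (0.63 ± 0.26) and Pmaip1 (1.38 ± 0.58). Smaller shifts were called for 34 Xist silencing factors (29 negative, mean -0.11, adjusted p 6.87e-04; 0.902 with an estimated correlation), 77 mitochondrial ribosomal proteins (mean -0.05, 0.00334; 0.976 with an estimated correlation) and 79 cytosolic ribosomal proteins (mean -0.06, 0.00349; 0.976 with an estimated correlation), whose genes have many near-identical pseudogenes and are uncertain for that reason. In each of these 8 lists, 0 members passed edgeR's test over all genes and 0 adjusted over the list alone, although 39 genes of G2 and mitosis and 39 of RNA polymerase I had an unadjusted p under 0.05, and DESeq2 called none of the genes named here. The calls for mitochondrial and cytosolic ribosomal proteins were lost without Female_WT 2 (adjusted p 0.503 and 0.679), the latter also without Female_KO 2 (0.162), and their means were -0.09 and -0.11 without Female_WT 1. Female_KO 1, set apart on the first component, had the lowest G2 and mitosis score (-0.50) and the lowest S phase score (-0.46) of all libraries.

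In male cells, 3 genes passed the test as well, Sirt7, Pcyt2 and Fam195b. Sirt7 fell by 4.03 ± 0.16 on the log2 scale (SE, adjusted p 8.04e-07). Pcyt2 fell from 49.1 ± 7.32 to 11.1 ± 2.93 CPM (SD, n = 3), a log2 change of -2.15 ± 0.25 (adjusted p 0.0250), and Fam195b rose 1.96-fold, from 50.8 ± 3.69 to 99.4 ± 13.9 CPM, a log2 change of 0.97 ± 0.11 (adjusted p 0.0150). Among the 5 genes of smallest p, Copz2, a coat subunit of COPI vesicles, had a log2 change of 0.48 ± 0.06 (adjusted p 0.0518), with 102 ± 7.76 CPM in WT and 142 ± 6.16 CPM in KO libraries, and P4hb one of 0.67 ± 0.09 (adjusted p 0.0610). Xist, at background counts in males, had a log2 change of 0.09 ± 0.15 (adjusted p 0.874; -0.00075 without Male_WT 1). The Y-linked genes had changes of 0.07 ± 0.25 (Ddx3y), 0.12 ± 0.24 (Eif2s3y), 0.37 ± 0.19 (Kdm5d) and 0.19 ± 0.28 (Uty), with adjusted p of 0.529 to 0.945. In edgeR's quasi-likelihood test 1554 genes had an unadjusted p under 0.05. DESeq2 called 111 genes, 85 higher and 26 lower, with P4hb and Copz2 among the higher ones. With TMM over autosomal genes edgeR called 5, 3 higher and 2 lower, with Copz2 and P4hb added, and with DESeq2 size factors 4, 2 higher and 2 lower, with Copz2 added. Sirt7 was called whichever library was left out. Fam195b and Pcyt2 were both lost without Female_WT 1 (adjusted p 0.0565 and 0.0615), Female_KO 3 (0.0596, 0.0733), Male_WT 1 (0.112, 0.105), Male_WT 3 (0.0825 for both) or Male_KO 2 (0.0591, 0.175), each time with a count of 1. Pcyt2 was also lost without Female_WT 2 (0.0703), Male_WT 2 (0.0703) or Male_KO 1 (0.105). Without both Female_KO 1 and Male_WT 3, Sirt7 alone was called, with Fam195b at 0.0784 and Pcyt2 at 0.0606, as it was in a fit to the 6 male libraries (0.378 and 0.192).

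Among the lists higher in male KO libraries by camera with its preset correlation were cholesterol synthesis and matrix genes. None of the male list calls held with an estimated correlation. In 9 of 10 splits of the male libraries, the real one among them, camera called as many lists. All 25 cholesterol synthesis genes were positive, with a mean of 0.75 (camera adjusted p 8.33e-16; adjusted p = 0.903 with an estimated correlation), and 24 of them passed adjusted over the list alone, against 0 over all genes. Examples are squalene epoxidase Sqle (0.64 ± 0.17) and the transcription factor Srebf2 (0.47 ± 0.13), each with an adjusted p of 0.0258 over the list alone. The score of the list was 0.56 in Male_KO 2 and 0.81 in Male_KO 3 but -0.13 in Male_KO 1, against -0.41, -0.09 and -0.37 in male WT libraries (exact permutation p 0.2, smallest possible 0.1). Male_KO 2 and Male_KO 3, set apart on the second component, also had skeletal muscle markers at -1.78 and -2.00, against 0.996 in Male_KO 1. Of 4 genes of steroid cells, chosen after their values were seen and in no fixed list, Cyp11a1 and Star were higher in the same libraries, with Cyp11a1 at 10.3 and 30.8 CPM (4.70 in Male_KO 1, 1.57 to 3.31 in male WT) and Star at 4.36 and 14.8 CPM (2.48 in Male_KO 1, 1.39 to 1.89 in male WT). Cyp11b1 (1.89 and 8.02 CPM) and Nr5a1 (0.935 and 2.75 CPM) set Male_KO 3 apart but not Male_KO 2, with 2.097 and 1.398 CPM in Female_WT 1. Of 63 extracellular matrix genes 57 were positive, with a mean of 0.38 (3.73e-11; 0.485 with an estimated correlation), and 7 passed adjusted over the list alone, among them lysyl oxidase Lox (0.54 ± 0.08) and the collagens Col16a1 (0.47 ± 0.10), Col1a2 (0.45 ± 0.11) and Col1a1 (0.46 ± 0.11). Of 49 genes of the unfolded protein and integrated stress response 36 were positive, with a mean of 0.26 (3.79e-04; 0.903 with an estimated correlation) and 0 passing over the list alone, among them the transcription factor Atf4 (0.44 ± 0.11) and its targets Chac1 (1.29 ± 0.35) and Trib3 (1.63 ± 0.47). Genes of RNA polymerase I and rRNA processing were lower, with 76 of 79 negative and a mean of -0.22 (1.62e-16; 0.903 with an estimated correlation), among them Rrp9 (-0.48 ± 0.13) and the initiation factor Rrn3 (-0.27 ± 0.08). Of the list members named here, DESeq2 called Lox, Col16a1, Col1a2, Col1a1, Chac1 and Trib3, but not Sqle, Srebf2, Atf4, Rrp9 or Rrn3. Of 77 mitochondrial ribosomal protein genes 66 were negative (mean -0.09, 1.64e-05; 0.903 with an estimated correlation), and of 62 S phase genes 57 (mean -0.15, 0.00643; 0.928 with an estimated correlation). The 53 interferon response genes had a mean of 0.12 (0.00643; 0.903 with an estimated correlation), which turned to -0.10 without Male_WT 3, -0.0077 without Male_WT 1 and -0.010 without Male_KO 2. The 70 genes of G2 and mitosis had a mean of 0.00 (adjusted p 0.670). The S phase call was lost without Male_WT 1 (adjusted p 0.542), Male_WT 2 (0.898) or Male_KO 3 (0.494). The mean for RNA polymerase I was -0.12 without Male_WT 1 and -0.15 without Male_KO 3. That for matrix genes was 0.58 without Male_WT 2 and 0.23 without Male_KO 1, that for interferon response 0.69 without Male_WT 2, and that for S phase -0.33 without Male_WT 3. The 7 lists called became 11 without Male_WT 2, 13 without Male_WT 3 and 12 without Male_KO 1. Male_WT 3, set apart on the first component, had the lowest matrix score.

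**Figure D2:**
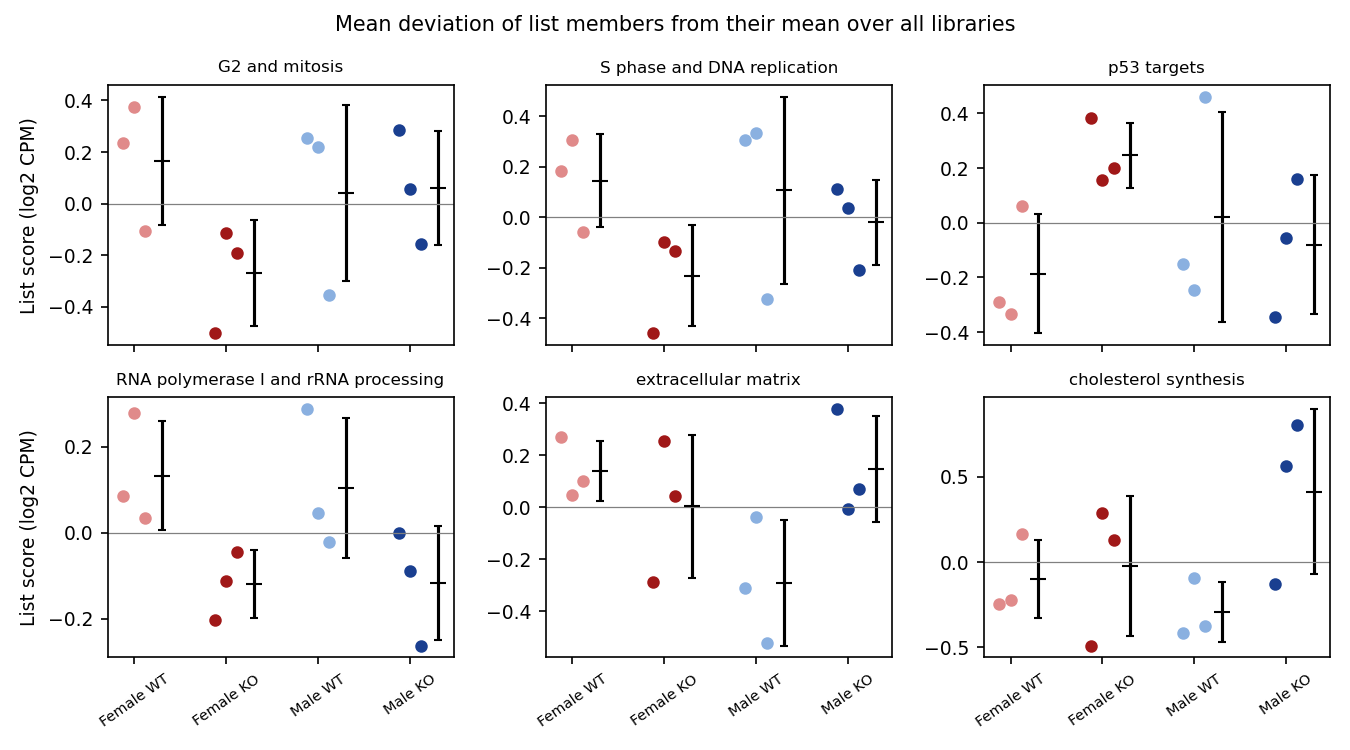
Mean log2 CPM deviation of the members of 6 gene lists in each of the 12 libraries (points, 3 per group), with the group mean and SD (black). Female_KO 1 has the lowest G2 and mitosis score (-0.50), and Male_WT 3 has the lowest extracellular matrix score (-0.52).

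Averaged over both sexes, 4 genes changed, all within 100 kb on chromosome 11. Sirt7 fell by 3.94 ± 0.11 (adjusted p 2.41e-08) and Pcyt2 by 2.15 ± 0.18 (8.42e-04) on the log2 scale (SE, n = 6). Fam195b rose 1.91-fold (0.94 ± 0.07, 6.60e-04), and P4hb rose 1.54-fold (0.63 ± 0.07, 0.00579), from 989 ± 52.7 to 1476 ± 33.1 CPM in females and from 890 ± 86.7 to 1419 ± 149 CPM in males (SD, n = 3). Xist had a change of 0.01 ± 0.09 (adjusted p 0.979), which turned to -0.01 without Female_WT 2, Female_WT 3 or Male_KO 2, -0.05 without Female_KO 2 and -0.04 without Male_WT 1. Arhgdia, which lies between them, had a log2 change of 0.56 ± 0.08 (adjusted p 0.0866). By rising coordinate the order is Fam195b (120542888 to 120549727), P4hb (120560298 to 120573253), Arhgdia (120578104 to 120581624), Pcyt2 (120610087 to 120617936) and Sirt7. All lie on the minus strand, so Pcyt2 lies downstream of Sirt7, with 435 bp between Pcyt2 and Sirt7. Alyref (-0.22 ± 0.09) and Anapc11 (-0.04 ± 0.07), which lie between Arhgdia and Pcyt2, and Mafg (-0.17 ± 0.06), on the other side of Sirt7, did not pass the test. With a minimum fold of 1.2 the P4hb call was lost (adjusted p 0.0830). By edgeR's quasi-likelihood test 1772 genes had an unadjusted p under 0.05, and DESeq2 called 38 genes, 21 higher and 17 lower, 11 of them on chromosome 11. All 4 genes were called whichever library was left out, with highest adjusted p of 0.00552 for Fam195b, 0.00765 for Pcyt2 and 0.0395 for P4hb. Across 15613 genes, which are not independent replicates, the female and male log2 changes had a Pearson correlation of -0.09 and a Spearman correlation of 0.05, and 54.2% had the same sign, in the 1 relation of this kind computed.

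**Figure D3:**
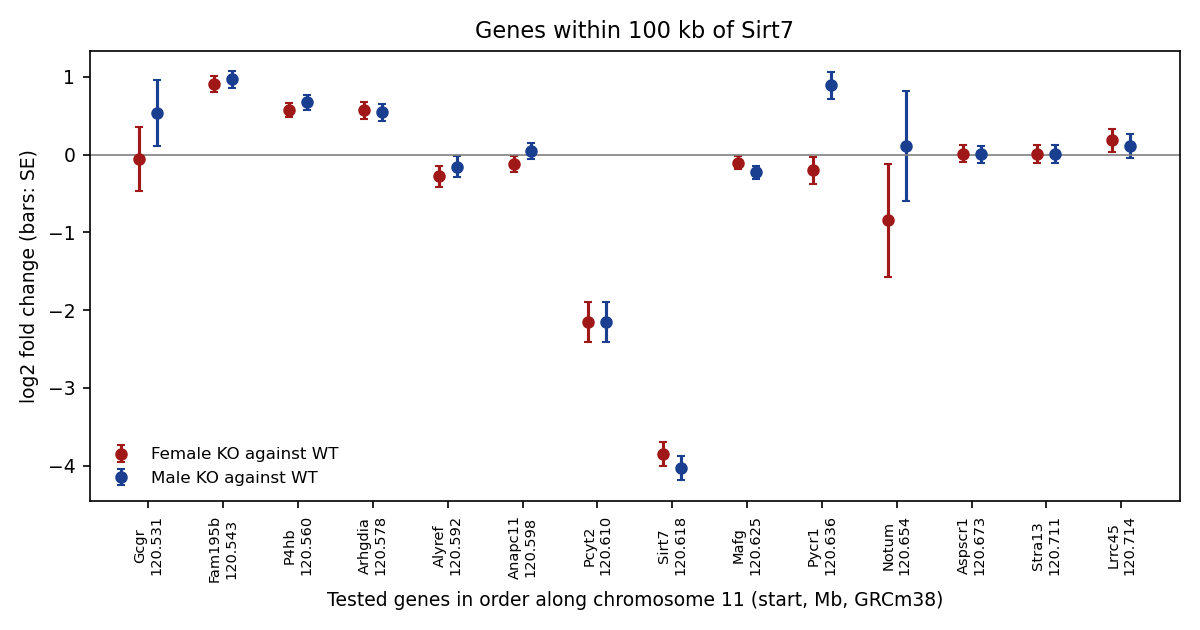
Log2 fold change of KO against WT with its SE for the tested genes within 100 kb of Sirt7, in order along chromosome 11 (start in Mb, GRCm38), in females (red) and males (blue). Sirt7 (-3.85 and -4.03) and Pcyt2 (-2.16 and -2.15) are lower and Fam195b (0.91 and 0.97), P4hb (0.58 and 0.67) and Arhgdia (0.57 and 0.54) are higher, with near-equal size in both sexes.

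Over both sexes, the list with the smallest p by camera with its preset correlation was RNA polymerase I and rRNA processing, where 78 of 79 genes were negative, with a mean of -0.24 (camera adjusted p 7.22e-31; adjusted p = 0.890 with an estimated correlation). Adjusted over the list alone 66 members were lower, against 0 over all genes, among them Ddx52 (-0.23 ± 0.05), Rrn3 (-0.24 ± 0.06), Rrp8 (-0.28 ± 0.07) and Tbl3 (-0.25 ± 0.06). Of these, DESeq2 called Ddx52 (adjusted p 0.0149) but not Rrn3, Rrp8 or Tbl3. In within-sex permutation of the list scores, this list had an exact p of 0.01 (mitochondrial ribosomal proteins 0.015). That was above the p of the sirtuins, which hold Sirt7 itself (0.005). After adjustment 0 of 33 lists passed (smallest 0.165). The smallest possible p of 0.005 itself became 0.165 here, so unless several lists had reached it none could pass. The count of 0 therefore does not weigh against any list. Genes of S phase (61 of 62 negative, mean -0.26, 1.78e-14; 0.890 with an estimated correlation), G2 and mitosis (70 of 70, -0.22, 7.80e-11; 0.930) and DNA repair (53 of 70, -0.10, 1.20e-04; 0.890) were also lower by camera. Mitochondrial ribosomal protein genes were lower by camera as well (66 of 77, mean -0.07, 6.31e-07; 0.890 with an estimated correlation). Cholesterol synthesis genes (25 of 25 positive, mean 0.43, 9.34e-10; 0.890 with an estimated correlation) and extracellular matrix genes (53 of 63, 0.15, 1.14e-04; 0.890) were higher by camera, with Lox (0.31 ± 0.06) alone passing over its list. The same permutation gave these lists an exact p of 0.115 (S phase), 0.235 (G2 and mitosis), 0.135 (DNA repair), 0.125 (cholesterol synthesis) and 0.335 (matrix), and the mean for G2 and mitosis was -0.44 in females and 0.00 in males. The mean for cholesterol synthesis was 0.10 in females and 0.75 in males, and that for matrix genes -0.08 in females and 0.38 in males. The matrix call was lost without Male_KO 1 (adjusted p 0.0633). The calls for p53 targets (mean 0.15, 0.0131; 0.930 with an estimated correlation), histone genes (0.17, 0.0365; 0.890), Xist silencing factors (-0.07, 0.0159; 0.930), cytosolic ribosomal proteins (-0.06, 0.0158; 0.930) and skeletal muscle markers (-0.64, 0.0490; 0.930) were each lost on leaving out single libraries, and these lists had an exact permutation p of 0.345, 0.07, 0.215, 0.12 and 0.31. For p53 targets these were Female_WT 1 (adjusted p 0.0926), Female_KO 1 (0.0882), Male_WT 1 (0.0524), Male_WT 2 (0.507) and Male_KO 3 (0.143). For Xist silencing factors they were Female_KO 1 (0.119), Male_WT 1 (0.104), Male_WT 2 (0.0898) and Male_KO 3 (0.106), and for cytosolic ribosomal proteins Female_WT 2 (0.333), Female_KO 2 (0.138), Male_WT 1 (0.0725), Male_WT 3 (0.157) and Male_KO 1 (0.0540). For histone genes they were Female_WT 2 (0.0703), Female_WT 3 (0.0812), Female_KO 1 (0.0882), Male_WT 1 (0.0524), Male_WT 2 (0.0898), Male_KO 1 (0.0809) and Male_KO 2 (0.0792). For skeletal muscle markers they were Female_WT 1 (0.0896), Female_WT 3 (0.233), Female_KO 1 (0.336), Male_WT 1 (0.248), Male_WT 2 (0.0920), Male_KO 2 (0.242) and Male_KO 3 (0.226). The mean for p53 targets was 0.28 and that for histone genes 0.26 without Male_WT 3, and that for DNA repair -0.07 without Male_WT 2. The mean for matrix genes was 0.08 without Female_KO 2 and 0.25 without Male_WT 2, and that for skeletal muscle markers -1.55 without Male_KO 1. The 12 lists called became 7 without Male_WT 1. In each KO comparison fry called 1 list, the sirtuins (adjusted p 0.0132 in females, 0.0146 in males and 0.00102 over both).

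No gene passed the test of a difference between the female and male KO effects. By edgeR's quasi-likelihood test 868 genes had an unadjusted p under 0.05, with a smallest adjusted p of 0.778, and DESeq2 called 1, Copz2 (-0.49 ± 0.10, adjusted p 0.0277). The 5 genes of smallest p were Copz2 (-0.48 ± 0.09), Lmo4, a LIM domain transcription cofactor (-0.42 ± 0.09), Rcn3, a calcium-binding protein of the endoplasmic reticulum (-0.41 ± 0.09), Pycr1, an enzyme of proline synthesis that lies beside Sirt7 (-1.09 ± 0.25), and the protocadherin Pcdh11x (-1.12 ± 0.26), all more negative in females. For Sirt7 the difference was 0.18 ± 0.20 (adjusted p 0.831) and for Xist -0.16 ± 0.19 (0.839). As lists, G2 and mitosis genes (female mean -0.44, male 0.00) had a difference of -0.44 (camera adjusted p 1.03e-16; adjusted p = 0.789 with an estimated correlation), with all 70 members negative. Cholesterol synthesis genes had a difference of -0.65 (2.28e-09; 0.789 with an estimated correlation), extracellular matrix genes of -0.46 (2.28e-09; 0.731), stress response genes of -0.29 (2.34e-05; 0.789) and p53 targets of 0.58 (4.31e-08; 0.789), with Pmaip1 at 3.16 ± 0.84 and Perp at 2.42 ± 0.73. In all, 13 lists were called, 4 higher and 9 lower in females than in males, 0 with an estimated correlation and 0 by fry, with 0 members passing over their lists. Without Female_KO 1 and Male_WT 3, which enter this comparison with the same sign, 6 of the 13 calls were kept, although 0 held with an estimated correlation (adjusted p 0.5725 to 0.8991). Without both, the differences were -0.17 for G2 and mitosis, 0.21 for p53 targets, -0.43 for cholesterol synthesis, -0.32 for matrix and -0.18 for stress response genes, and 0.77 for neuron markers. Without Male_WT 3 alone they were -0.28 for G2 and mitosis and 0.30 for p53 targets.

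No shift of X-linked against autosomal genes was detected on loss of SIRT7. The median log2 change of 537 X-linked genes minus that of 15072 autosomal genes was -0.01 in females (camera p 0.437, and 0.504 with an estimated correlation), 0.03 in males (0.369, 0.443) and 0.01 over both (0.929, 0.938). The female minus male difference was -0.05 (0.182, 0.264). In females 267 X-linked genes (49.7%) had a positive change, against 52.5% of autosomal genes, and in males 282 (52.5%) against 47.7%. Over all 6 comparisons the smallest adjusted p was 0.614. No X-linked gene passed the edgeR test in the KO comparisons when adjusted over X-linked genes alone, and of 537 in female KO 9 were higher and 25 lower at an unadjusted p under 0.05, with 0 X-linked genes among those that DESeq2 called. The 16 genes known to escape X inactivation had a mean change of -0.06 in females (3 positive, 13 negative, camera adjusted p 0.236) and the 8 genes of the X inactivation centre one of 0.02 (0.708). The log2 ratio of median X-linked to median autosomal expression was -0.35 ± 0.06 in female WT, -0.39 ± 0.05 in female KO, -0.40 ± 0.05 in male WT and -0.39 ± 0.02 in male KO libraries (SD, n = 3). KO minus WT was -0.04 in females (exact permutation p 0.4, 90% exact interval -0.14 to 0.07) and 0.01 in males (exact permutation p 0.8, interval -0.06 to 0.08), where the smallest possible p is 0.1. Over both sexes it was -0.01 (exact permutation p 0.635). Some of these signs turned when single libraries were left out. The female median shift was 0.0073 without Female_WT 1 and 0.0026 without Female_KO 1, that over both sexes -0.0024 without Female_KO 2 and -0.0020 without Male_WT 3, the male ratio -0.01 without Male_WT 3, and the ratio over both sexes 0.0013 without Female_KO 1. No library turned the female ratio (-0.07 to -0.0088), the male median shift (0.01 to 0.03) or the female minus male difference (-0.07 to -0.03).

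**Figure D4:**
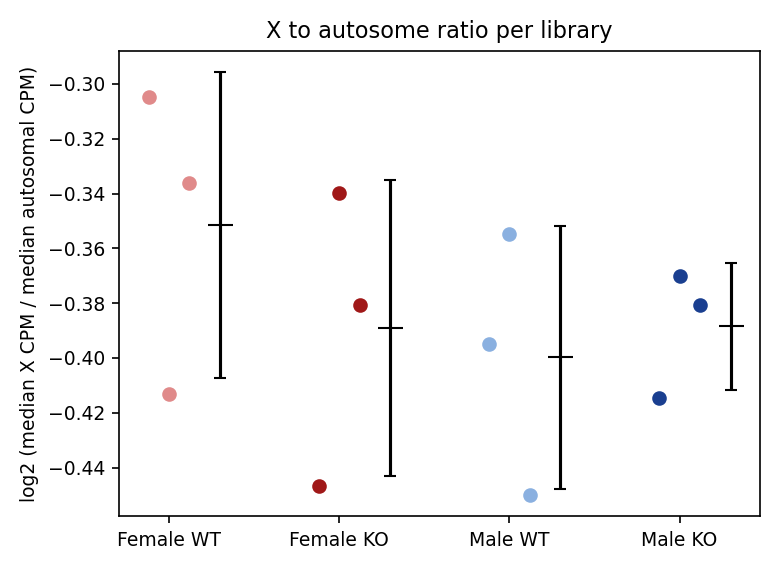
Log2 ratio of the median CPM of 447 X-linked genes to that of 12517 autosomal genes in each of the 12 libraries (points, 3 per group), with the group mean and SD (black). Group means lie between -0.40 and -0.35, with SDs of 0.02 to 0.06.

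By edgeR's test, female and male WT cells differed in sex chromosome genes. Xist was higher in females by 8.53 ± 0.16 on the log2 scale (SE, adjusted p 3.97e-10), 371-fold, at 581 ± 55.6 against 1.56 ± 0.185 CPM (SD, n = 3). The escape gene Kdm5c, a histone demethylase, was 1.41-fold higher in females (0.50 ± 0.06, adjusted p 0.00814), at 243 ± 11.4 against 172 ± 2.49 CPM. The Y-linked genes, given above as counts, were lower in females, with adjusted p of 1.04e-07 (Kdm5d), 8.39e-07 (Eif2s3y), 1.01e-06 (Ddx3y) and 4.25e-06 (Uty). These 6 genes were all that edgeR's quasi-likelihood test called, with 645 at an unadjusted p under 0.05. DESeq2 called 27, most of them autosomal and 5 X-linked. Sirt7 had a difference of -0.12 ± 0.14 (adjusted p 0.991), which turned to 0.02 without Male_WT 3. Adjusted over X-linked genes alone, Kdm6a, a further histone demethylase (0.72 ± 0.10, 0.00509), and Pbdc1 (0.54 ± 0.11, 0.0441) were higher in females besides Xist and Kdm5c. DESeq2 called Kdm6a and Pbdc1 over all genes (adjusted p 2.32e-06 and 0.00637). Of the 16 escape genes, which include Xist, 12 were positive, with a mean of 0.77, and 7 passed adjusted over the list alone (camera adjusted p 2.12e-12), the 1 list of this comparison whose call held with an estimated correlation (adjusted p = 0.00476). Without Xist the other 15 had a mean of 0.25, with 11 positive and 6 passing over the list alone (camera adjusted p 6.59e-08; adjusted p = 0.0188 with an estimated correlation). The 8 genes of the X inactivation centre, which include Xist, had a mean of 1.37 (9.96e-04; 0.0902 with an estimated correlation), and the other 7 had one of 0.35 (0.3998; 0.915 with an estimated correlation). Extracellular matrix genes (53 of 63 positive, mean 0.36, 8.45e-16; 0.0901 with an estimated correlation) had 6 members higher over the list alone, among them Col1a1 (0.51 ± 0.11) and Col5a1 (0.43 ± 0.09), and stress response genes (41 of 49, 0.32, 4.49e-10; 0.162 with an estimated correlation) had 14 higher and 1 lower, among them the serine and asparagine synthesis genes Psph (0.67 ± 0.15) and Asns (0.90 ± 0.22). The Kdm5c call was lost without Female_WT 1 (adjusted p 0.0537), Female_WT 3 (0.0626) or Male_WT 3 (0.0557), without both Female_KO 1 and Male_WT 3 (0.0787), in a fit to the 6 WT libraries (0.581) and with a minimum fold of 1.2 (0.348). The matrix mean was 0.55 without Male_WT 2.

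Another 8 lists were called between female and male WT cells, each with an adjusted p of 0.773 or 0.915 with an estimated correlation. Chondrocyte markers (mean 1.13, camera adjusted p 0.00134), cholesterol synthesis genes (0.20, 0.00761), G2 and mitosis genes (0.11, 6.72e-04) and Xist silencing factors (0.08, 4.09e-04) were higher in females. Macrophage markers (-0.76, 1.77e-04), p53 targets (-0.25, 3.97e-04), oxidative phosphorylation genes (-0.06, 8.92e-04) and mitochondrial ribosomal proteins (-0.05, 0.0170) were lower. Without Male_WT 3 the mean for p53 targets was 0.03 and that for G2 and mitosis -0.06, and the calls for Xist silencing factors (adjusted p 0.215) and oxidative phosphorylation (0.180) were lost. Without Female_WT 1 the mean for chondrocyte markers was -0.04, and oxidative phosphorylation (0.683) and mitochondrial ribosomal proteins (0.718) were lost. Calls were also lost without Female_WT 2 for p53 targets (0.0610) and G2 and mitosis (0.719), without Female_WT 3 for mitochondrial ribosomal proteins (0.187), cholesterol synthesis (0.475) and macrophage markers (0.0933), and without Male_WT 1 for mitochondrial ribosomal proteins (0.814) and cholesterol synthesis (0.172). Some values moved with the call kept. These were the means for macrophage markers (-1.35 without Female_WT 2, -0.44 without Male_WT 3), p53 targets (-0.39 without Female_WT 3), cholesterol synthesis (0.32 without Male_WT 2), Xist silencing factors (0.14 without Male_WT 1), G2 and mitosis (0.24 without Female_WT 3, 0.22 without Male_WT 1, 0.20 without Male_WT 2), and oxidative phosphorylation and mitochondrial ribosomal proteins (-0.09 for both without Female_WT 2). By fry 3 lists were called, the escape genes and the X inactivation centre, both of which hold Xist (adjusted p 2.67e-06 for both), and the extracellular matrix (0.0479).

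By edgeR's test, the difference between the sexes in KO cells again lay in Xist and the Y-linked genes. Xist was higher in females by 8.37 ± 0.16 (SE, adjusted p 4.53e-10), and the 4 Y-linked genes were lower. Sirt7 differed by 0.06 ± 0.15 (adjusted p 0.939), and by -0.0025 without Female_KO 1 and -0.03 without Male_KO 2. These 5 genes were called by edgeR's quasi-likelihood test, with 1234 at an unadjusted p under 0.05, and edgeR called 11 without Male_KO 1. DESeq2 called 66, most of them autosomal and 5 X-linked. Adjusted over X-linked genes alone, Kdm6a (0.61 ± 0.10, 0.0165), Eif2s3x, a translation initiation factor gene (0.68 ± 0.10, 0.00855), and Kdm5c (0.37 ± 0.06, 0.00855) were higher in females besides Xist, with Kdm5c at 237 ± 1.77 against 183 ± 8.12 CPM and Kdm6a at 78.0 ± 8.94 against 51.2 ± 1.15 CPM (SD, n = 3). DESeq2 called Kdm6a, Eif2s3x and Kdm5c over all genes (adjusted p 6.50e-04, 7.50e-06 and 3.69e-07). Of the 16 escape genes, Xist among them, 10 were positive, with a mean of 0.63 and 6 passing adjusted over the list alone (camera adjusted p 1.49e-04; adjusted p = 0.167 with an estimated correlation). Without Xist the other 15 had a mean of 0.11, with 9 positive and 5 passing (0.0214; 0.799 with an estimated correlation). X-linked against autosomal genes gave a shift of -0.05 between female and male KO (camera p 0.246) and of 0.00 between female and male WT cells (0.511; -0.01 without Female_WT 1 and -0.0028 without Male_WT 3). Genes of G2 and mitosis (0 of 70 positive, mean -0.33, 1.98e-15), cholesterol synthesis (0 of 25, -0.45, 2.89e-08), S phase (3 of 62, -0.21, 5.15e-07), interferon response (9 of 53, -0.39, 1.18e-04), germline (2 of 15, -0.66, 0.00533) and DNA repair (19 of 70, -0.10, 0.0209) were lower in females, all with an adjusted p of 0.752 with an estimated correlation. The p53 targets (34 of 40 positive, mean 0.33, 6.50e-05), contractile genes (26 of 30, 0.19, 0.00501) and neuron markers (11 of 13, 0.51, 0.0270) were higher, with the same adjusted p of 0.752 with an estimated correlation. The p53 call was lost without Male_KO 1 (adjusted p 0.104), DNA repair without Female_KO 1 (0.195), Male_KO 1 (0.160) or Male_KO 2 (0.141), and contractile genes without Female_KO 1 (0.328) or Male_KO 3 (0.131). Calls were also lost for germline genes without Female_KO 1 (0.281) or Male_KO 2 (0.143) and neuron markers without Female_KO 2 (0.0957), Female_KO 3 (0.0647) or Male_KO 2 (0.278). With the call kept, the mean for S phase was -0.11 without Female_KO 1 and -0.14 without Male_KO 1, and that for G2 and mitosis -0.21 without Male_KO 1. The mean for cholesterol synthesis was -0.26 without Male_KO 3 and -0.265 without Female_KO 1, that for contractile genes 0.30 and that for neuron markers 0.82 without Male_KO 1, and that for germline genes -1.02 without Female_KO 2. The lists of inflammatory secretion, glycolysis, imprinted genes, Hox genes and markers of endothelium, smooth muscle, epithelium, adipocytes and erythroid cells were called in 0 of the 6 comparisons, with a smallest camera adjusted p of 0.0555.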

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

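The tests that weigh causes here were chosen after the results were seen, while the splits of the libraries were planned. For 13 gene lists the female and male KO effects differed by camera's test of the difference, although 0 calls held with an estimated correlation (adjusted p 0.731 to 0.924). Female minus male, the values were -0.44 for G2 and mitosis, -0.22 for S phase, -0.13 for DNA repair, 0.58 for p53 targets, -0.65 for cholesterol synthesis, -0.46 for extracellular matrix, -0.29 for the stress response, -0.37 for interferon response and -0.093 for Xist silencing factors. They were 0.067 for oxidative phosphorylation, 0.77 for neuron markers, 1.37 for glia markers and -1.44 for chondrocyte markers. The glia and chondrocyte markers differed through genes such as Fabp7 (2.52 ± 0.81) and Hapln1 (-2.66 ± 0.85), none of which passed over its list. Female_KO 1 and Male_WT 3, which stand apart from the other 10 libraries, lie in arms of this comparison where they push in the same direction. A candidate explanation of the 13 differences is thus these libraries alone. Without both, 6 lists lost their call with a value that turned (S phase 0.06, oxidative phosphorylation -0.00058, glia markers -0.02) or fell under 0.5 times (Xist silencing factors -0.0086, DNA repair -0.021, interferon response -0.11), so for these 6 the libraries may account for the call. As differences of list scores (SE), S phase went from -0.25 ± 0.28 to 0.08 ± 0.19, interferon response from -0.52 ± 0.47 to -0.14 ± 0.46 and glia markers from 1.06 ± 0.80 to 0.24 ± 0.71. Chondrocyte markers, 1 list more, lost the call with a difference of -1.33 against -1.44 (scores -1.06 ± 0.75 with all and -0.80 ± 0.93 without), so their lost call is no sign that these libraries account for it. The other 6 kept call and direction without both by camera with its preset correlation (p53 targets 0.21, G2 and mitosis -0.17, stress response -0.18, matrix -0.32, cholesterol synthesis -0.43, neuron markers 0.77), but 0 of them held with an estimated correlation (adjusted p 0.5725 to 0.8991). Without both libraries the values of G2 and mitosis and p53 targets were 0.39 and 0.36 times those with all, so these libraries may account for most of them too. How much of the other kept lists they account for stays open, as does a difference between the sexes. Depth and a swap of their labels are argued against by a total of 45.25 M counts in the deeper library and by the 88 Sirt7 counts of Female_KO 1 (a KO level). A lower share of fibroblasts that raises every other cell type alike is argued against by 2 cell type lists (epithelium and chondrocytes) below all other libraries in both, while those of macrophages and of glia and neural crest lay above all others. No cell type list was of fibroblasts, so a lower share in any other form was not tested and stays open. The matrix genes Lum (1.95 and 1.35 CPM) and Dcn (10.4 and 7.09 CPM) were lower in both than in all other libraries. More macrophages and neural crest cells in both stay open as a candidate explanation. Of 27 of their markers, 18 were above all other libraries in both, as were 14.2% of 12968 genes with a mean CPM of 1 or more, among them Lyz2 (48.2 and 49.5 CPM, others 1.59 to 33.5) and Ngfr (74.6 and 52.4 CPM, others 4.34 to 23.0), but these lists were picked for being high, and 26 of the markers were counted in each of the other libraries too. What makes the libraries stand apart stays open.

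Single libraries also ended calls among the 13. Without Male_WT 3 these were S phase (adjusted p 0.410), DNA repair (0.2995), interferon response (0.0613), oxidative phosphorylation (0.2995), Xist silencing factors (0.372) and glia markers (0.144). Without Female_KO 1 they were DNA repair (0.0745), oxidative phosphorylation (0.419), Xist silencing factors (0.0996) and glia markers (0.0659). Without Male_KO 1 they were oxidative phosphorylation (0.217), Xist silencing factors (0.226) and chondrocyte markers (0.0563), and without Male_KO 2 DNA repair (0.0572), neuron (0.306) and glia markers (0.159). Without Female_WT 1 oxidative phosphorylation (0.730), neuron (0.0769) and chondrocyte markers (0.267) lost their call, without Female_WT 2 Xist silencing factors (0.0860), neuron (0.0793) and glia markers (0.189), and without Female_WT 3 neuron (0.0576) and glia markers (0.0623). Neuron markers were also lost without Female_KO 2 (0.119), Female_KO 3 (0.112) or Male_WT 1 (0.155), glia markers without Male_WT 2 (0.0843) or Male_KO 3 (0.0914), and oxidative phosphorylation without Male_WT 1 (0.0559). With the call kept, the difference for S phase was -0.13 without Female_WT 2, -0.12 without Female_KO 1 and -0.34 without Male_WT 2, that for DNA repair -0.20 without Male_WT 2, and that for interferon response -0.18 without Female_WT 2, -0.24 without Male_WT 1, -0.94 without Male_WT 2 and -0.25 without Male_KO 2. That for Xist silencing factors was -0.14 without Male_WT 1 and -0.15 without Male_KO 3, that for oxidative phosphorylation 0.10 without Female_WT 2, and that for glia markers 2.155 without Female_WT 1.

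Genes beside Sirt7 changed in KO libraries. By edgeR's test Pcyt2 was lower and Fam195b higher in each sex. P4hb was higher over both sexes by that test (adjusted p 0.292 in females and 0.0610 in males), and Arhgdia passed in none (0.635, 0.438 and 0.0866 over both). DESeq2 called both P4hb and Arhgdia in each sex and over both, P4hb with an adjusted p of 1.98e-04 in females and 2.45e-07 in males. Chance is argued against by location, since 11 of 4389 windows of 100 kb around tested genes had a mean signal as high, and all 11 were centred within 200 kb of Sirt7. A move of reads from Sirt7 to P4hb is argued against by size, since P4hb gained at least 10.2 times the CPM that Sirt7 lost. A candidate explanation is DNA or regulation linked to the targeted allele, such as a vector sequence or flanking DNA of another strain, which the design cannot tell apart from an effect of the lost protein because every KO library has the allele. Within 100 kb of Sirt7 7 of 13 genes had an unadjusted p under 0.05, against 11.9% of 1198 genes beyond 1 Mb on the chromosome, so the changes lie near the gene. Among the 7, Pycr1 had log2 changes of -0.20 ± 0.17 in females and 0.89 ± 0.18 in males, so its change was not shared by both sexes. The rest had the same sign in both sexes.

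In other splits of the libraries, 3 against 3 libraries give 10 splits, too few for a share under 0.05. The real split called 3 genes in female KO, 3 in male KO, 6 between the sexes in WT and 5 in KO cells, where the highest of the other splits called 0, so 1 of 10 splits gave as many in each. Over both sexes, 4 of 200 splits within sex gave 4 or more genes, a share under 0.05. Sirt7, the targeted gene, is among the 4 of the real split, so this share cannot exclude chance for the other genes. In 193 of 200 splits no gene was called, yet the highest other split called 973. That split exchanges Male_WT 3 and Male_KO 1, puts Female_KO 1 and Male_WT 3 on 1 side and points to a structure of the samples. For the difference between sexes the count was 0, so 200 of 200 splits gave as many, with a highest other of 973. For lists the real split called 8 in female KO (10 of 10 splits gave as many, highest other 15), 7 in male KO (9 of 10, 15), 12 between the sexes in WT (7 of 10, 15) and 10 in KO cells (8 of 10, 18). Over both sexes it called 12 (103 of 200, 20) and for the difference 13 (67 of 200, 20). Chance is thus not excluded for the number of lists over both sexes or for the difference. For the size of the X-linked shift, 5 of 10 splits gave a value as large in female KO (highest other 0.04), 3 of 10 in male KO (0.04), 8 of 10 between the sexes in WT (0.05) and 1 of 10 in KO cells (0.03). Over both sexes 114 of 200 did (0.04), and for the difference 13 of 200 (0.08), so chance is not excluded for either.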

How the results depend on the processing

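Fits without both libraries that stand apart (Female_KO 1 and Male_WT 3) and with counts divided by 2, and lists without Xist, were chosen after the data were seen. Spike-in alternatives were not run, because the table used here holds no spike-in genes. Where no reason is given, the cause was not tested. Of the comparisons under an alternative, 333 stayed on their side and direction, 44 moved and 17 reversed. Of the single genes 651 stayed, 37 became weaker, 11 stronger and 15 reversed, and of the lists 826 stayed, 216 became weaker and 18 reversed. DESeq2 called 7 genes in female KO (3 by edgeR), 111 in male KO (3), 38 over both sexes (4), 1 for the difference (0), 27 between the sexes in WT (6) and 66 in KO cells (5). A fit to only the 6 libraries of a pair of groups, which has fewer samples, called 1 gene in female KO and 1 in male KO. With TMM over autosomal genes male KO had 5 genes, 3 higher and 2 lower. With an estimated correlation the number of lists was 0 in female KO, 0 in male KO, 0 over both sexes, 0 for the difference, 1 between the sexes in WT and 0 in KO cells, and without both libraries that stand apart it was 0, 0, 0, 0, 2 and 1. Without both libraries that stand apart female KO had 5 genes and male KO 1, and 13 lists were called in male KO. There the interferon effect in male KO was -0.10, the female minus male difference of the KO effect was 0.058 for S phase, -0.00058 for oxidative phosphorylation, -0.018 for glia markers and -0.026 for Sirt7, and Xist in female KO was 0.035. Between the sexes in WT it gave 0.026 for p53 targets, -0.057 for G2 and mitosis and 0.024 for Sirt7, and in KO cells -0.0025 for Sirt7. The shift of X-linked genes was 0.00021 in female KO and -0.0035 between the sexes in WT, and the X to autosome ratio in male KO changed by -0.014. With no low-count filter the shift was 0.0013 in female KO, 0 in male KO and 0 between the sexes in KO cells. Between the sexes in WT it was -0.0026 at a mean CPM of 1 or more and -0.0003497 without escape genes. The X to autosome ratio changed by 0.0044 in female KO and 0.025 over both sexes at a mean CPM of 5 or more, and by 0.0064 over both sexes with summed CPM. Leaving out each library in turn gave 1 to 6 genes in female KO, 1 to 4 in male KO and 5 to 11 between the sexes in KO cells, and 7 to 13 lists in male KO and 7 to 12 over both sexes. The X-linked shift ranged from -0.029 to 0.0073 in female KO, from -0.0024 to 0.018 over both sexes and from -0.010 to 0.023 between the sexes in WT. Xist ranged from -0.20 to 0.035 in female KO, from -0.00075 to 0.15 in male KO and from -0.054 to 0.066 over both sexes. The Sirt7 difference ranged from -0.21 to 0.024 between the sexes in WT and from -0.028 to 0.12 in KO cells. The interferon effect in male KO ranged from -0.10 to 0.69. In WT cells the sex difference ranged from -0.39 to 0.026 for p53 targets, from -0.057 to 0.24 for G2 and mitosis and from -0.043 to 1.44 for chondrocyte markers. The change of the X to autosome ratio ranged from -0.014 to 0.034 in male KO and from -0.029 to 0.0013 over both sexes. With the replicate block, the counts were 2 genes in female KO, 2 in male KO, 4 over both sexes, 0 for the difference, 6 between the sexes in WT and 5 in KO cells, and 8, 7, 11, 13, 13 and 11 lists. Fam195b was the gene not called there (adjusted p 0.141 in females, 0.0844 in males). The replicate numbers do not pair the samples, since same-numbered libraries had deviations correlated at -0.17, -0.21 and 0.16 in females and 0.34, -0.05 and 0.30 in males. Counts divided by 2 and a minimum fold of 1.2 left every gene count within 1.5 times its value. With a self-test recovery of 25.4% at 1.5-fold, most changes of that size would be missed at this depth and spread.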

Other observations

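Genes in these observations were chosen after their values were seen, as were the tests, except that on genes of low count in the chromosome 8 interval. Beyond the fixed comparisons, some single genes and some Hox genes were higher or lower in both libraries that stand apart than in the other 10. The single genes were not tested as a set. Female_KO 1 and Male_WT 3 had Cdkn2a, the locus of the cell cycle inhibitors p16 and Arf, at 31.7 and 37.1 CPM, against 5.59 to 20.6 CPM in the other 10 libraries, and the p53 target Cdkn1a at 521 and 503 CPM (others 218 to 403). The imprinted gene H19 (861 and 793 CPM, others 1455 to 2377) and the matrix proteoglycans Lum (1.95 and 1.35 CPM, others 6.37 to 85.2) and Dcn (10.4 and 7.09 CPM, others 27.2 to 142) were low in both, while Igf2, beside H19, was at 1602 and 1270 CPM, with 1461 and 1617 CPM in Male_KO 2 and Male_KO 3 and 2061 to 3033 CPM in the remaining libraries. Of 35 Hox genes with a mean CPM of 1 or more, which keep a record of position along the body axis in fibroblasts, 13 (37.1%) were higher in both than in all other libraries, against 14.2% of the 12968 genes at that level, although neighbouring Hox genes are not independent. Hoxb8 was at 67.9 and 48.3 CPM, against 14.8 to 26.9 CPM in the others.

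Single genes known from muscle and from steroid cells varied between libraries as well. The muscle regulator Myog was at 0.272 and 0.314 CPM in Female_KO 1 and Male_WT 3 and at 0.356 and 0.546 CPM in Male_KO 2 and Male_KO 3, against 3.15 to 21.5 CPM in the others, and cardiac actin Actc1 was at 14.3, 13.4, 15.1 and 16.6 CPM in the same libraries (others 32.8 to 105). Male_KO 2 and Male_KO 3 had Cyp11a1, the first enzyme of steroid synthesis, at 10.3 and 30.8 CPM (others 0.442 to 4.74) and the cholesterol carrier Star at 4.36 and 14.8 CPM (others 1.08 to 3.21), while Cyp11b1 and the regulator Nr5a1 set Male_KO 3 apart (8.02 and 2.75 CPM) but not Male_KO 2 (1.89 and 0.935 CPM, with 2.097 and 1.398 CPM in Female_WT 1).

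In Female_KO 2 and Female_KO 3, 5 neighbouring genes on chromosome 8 (Rwdd4a, Ing2, Cdkn2aip, Wwc2 and Dctd, 47533664 to 48153233, 619.6 kb, GRCm38) were lower together, with median log2 deviations of -0.87 and -0.77 (0.547-fold and 0.588-fold), against -0.09 to 0.19 in the other 10 libraries. A scan of 10855 windows of 5 genes found 7 runs in 4 libraries, 4 lower and 3 higher, of which 3 were of this block and 3 of the Hoxb cluster. Tenm3, the next gene after the interval, was at -0.37 and -0.80. Female_KO 2 and Female_KO 3 were also the most alike pair of replicates (chi-square per degree of freedom 18.9), so they may not be independent samples. A candidate explanation is the loss of 1 copy of this interval. The interval held 0 other tested genes, so such a loss could not be tested on genes of low count, and fewer reads are argued against by a total of 44.19 M counts in the deeper of these libraries. No biological explanation was tested, and DNA would have to be sequenced to settle it.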
